A study of Mus musculus with 2 samples.

How the data were processed

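Total RNA was extracted with Trizol from oocytes of mice aged 2 weeks on the C57BL/6 background, and libraries were made with a TruSeq RNA kit from 1 ug of RNA and sequenced on an Illumina HiSeq instrument, per the labels' protocols. The series holds 1 library of wild type oocytes and 1 library of oocytes from mice with *Gdf9*-Cre and loxP-flanked *Kat8* (cKO). The submitters' processing notes name the aligner Bowtie 0.12.2 and the mouse genome build mm10. How fragments were assigned to genes, with which annotation, and which test gave the p-values are not stated in the sources used here.

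The deposited data are 3 tables: all genes, and the genes the authors list as higher (500) and lower (358) in the cKO. Per the file headers, each gives 1 FPKM value per gene and library, the linear fold change of the knockout over the other library, a p-value and an FDR. The authors deposited values of 0 as 1e-05, read here as 0 FPKM: 1211 genes in the wild type and 1056 in the cKO library were listed at 0. The deposited fold change was checked to be the quotient of the FPKM columns. The column named KO was taken as the cKO library and the column named NC, by elimination, as the wild type library. The headers of the description and locus columns are exchanged in the tables. In the table of all genes, 27 gene names had been turned into dates and 2 gene IDs occurred more than once. A single line of that table held no values; it and a few genes that the naming rule would give are not reported here.

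No counts or library totals are given, so absolute depth is unknown and no counting interval is given. The FPKM columns sum to 666635 in the wild type and 562823 in the cKO library, and the 50 most abundant genes take 24.7% and 22.7% of these sums. Relative depth was read from 3502 genes under 0.6 FPKM in both libraries, whose ratios of cKO over wild type FPKM peaked at 0.619, 1.24 and 2.47. These are the ratios of 1 to 2, 1 to 1 and 2 to 1 fragments, so 1 fragment was worth 1.24 times as many FPKM in the cKO library.

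The measure is the log2 ratio of the cKO over the wild type library on the log2(FPKM + 0.1) scale. The ratios of single genes called folds are quotients of the FPKM values and are given only where both are above 0. A gene was called higher or lower when its FPKM was at least 1 in either library and its log2 ratio at least 1 or at most -1 (the rule of size). With 1 library per group there is no test between genotypes, and no paired analysis was possible. Before the data were examined, 34 gene lists, the rule of size, the test of X-linked genes and most alternatives were fixed. Of the lists, 33 had at least 5 members past the floor; the list of mitochondrially encoded subunits had 0 members in the table. The lists cover KAT8 complex partners, other histone acetyltransferases, histone deacetylases and sirtuins, mitochondrial and energy metabolism, antioxidant enzymes, oocyte and meiotic genes, DNA repair, p53 targets, apoptosis, stress responses, protein and organelle turnover, ribosomal proteins, imprinted genes, piRNA genes, 2-cell-stage transcripts, proliferation, and markers of other ovarian cells.

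The median log2 ratio of each list was set against 10000 random lists of the same size, matched in 20 bins of mean expression. A list stands apart when its percentile is under 2.5 or over 97.5. Of the 33 lists 10 stood apart, 4 lower and 6 higher. If the genes of a list varied independently, chance would give 1.7 such lists. Genes of a list may vary together, and some lists share members, so chance may give more. The percentiles describe these 2 libraries only. Bootstrap intervals (95%, 10000 draws) are over genes, which are not independent replicates.

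Gene positions, transcript lengths and GC contents came from GENCODE M21 (GRCm38, the assembly of mm10), matched by gene ID for 17349 genes. Of these, 99.5% overlapped the deposited locus. A length and GC content was available for 17294 genes. To group genes as X-linked, autosomal or by chromosome, the chromosome of the deposited locus was used. Matching on length or GC content used the 100 nearest genes. The genes named were chosen by a rule fixed beforehand. It names *Kat8*, and the 12 genes with the largest and the 12 with the smallest log2 ratio at 5 FPKM or more in the larger library, without predicted gene numbers, RIKEN clones, numbered pseudogenes and small RNAs. It also names up to 4 members with the largest absolute log2 ratios of each list that stands apart or bears on the genotype, the 5 most abundant genes of each library, and *Sod1*, *Sod2*, *Cat*, *Gpx1*, *Gdf9*, *Bmp15*, *Zp1*, *Zp2*, *Zp3*, *Cdkn1a*, *Bax* and *Bbc3*. The pseudogene *Oaz1-ps* passed this rule because its name carries no number. Names turned into dates were also left out; 0 of them would have been named. Other named genes are marked as chosen after their values were seen.

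Alternatives fixed beforehand were median-of-ratios scaling, library sizes without the 50 most abundant genes, no floor and a floor of 5 FPKM, pseudocounts of 1 and 0.01, a 4-fold rule, the authors' deposited fold change in place of the ratio, and random lists unmatched or matched also on length. FPKM rescaled to TPM, ratios less their trend on length and GC content (a polynomial of degree 3), and random lists matched on GC content, alone or with length, were added after the data were seen. The code was tested on simulated data for the 18467 genes: of 50 genes each with log2 changes of -2, -1.5, 1.5 and 2, the rule of size found 50, 49, 48 and 50, and 11 of 10796 unchanged genes passed it. Of 100 random lists 4 stood apart, as did 40 of 40 lists shifted by -0.5. The simulated ratios had less spread than the real ones and no trend on length or GC content. Changed genes were drawn only at 5 FPKM or more in the wild type. These shares therefore test the code and are not error rates of the calls reported here. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.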

Results

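The deposited data are gene expression values from oocytes of mice aged 2 weeks on the C57BL/6 background. The 1 wild type library and the 1 library of the conditional knockout, called cKO here, were compared. In the cKO, *Kat8* alleles flanked by loxP sites were deleted by Cre recombinase made under the *Gdf9* promoter, which is active in oocytes from the primordial follicle stage on. KAT8, also called MOF, is the acetyltransferase of lysine 16 of histone H4, and the comparison asks how the oocyte transcriptome differs where its gene is deleted. The table of all genes held 18467 genes, of which 10828 reached 1 FPKM (fragments mapped to a gene, scaled by transcript length and library size) in the wild type library and 11282 in the cKO library. The total number of fragments in each library is unknown. Among genes with very low values, 1 fragment was worth 1.24 times as many FPKM in the cKO library as in the wild type library, so low values are less precise in the cKO library. With 1 library per group the differences below have no replicate check, and the genotype and the individual library cannot be separated.

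*Kat8* (gene ID 67773) stood at 166 FPKM in the wild type library and 0.985 FPKM in the cKO library, 168-fold lower (log2 ratio -7.25). The gene lies on the plus strand of GRCm38 chromosome 7, 127912516 to 127925837, and the deposited values cover the whole gene. Which part of it the Cre recombinase removed is not given in the sources used here. *Bckdk*, which encodes the kinase of branched-chain ketoacid dehydrogenase and ends 2294 bases upstream of *Kat8*, was listed at 5.54 and 0.563 FPKM in the wild type and cKO libraries, 9.85-fold lower in the cKO. *Prss8*, which overlaps the end of *Kat8* on the other strand, was listed at 6.77 and 8.81 FPKM. Strand-specific counting is not stated for these libraries, so reads from the overlap cannot be assigned to either gene. *Bckdk* and *Prss8* were chosen after their values were seen.

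Oocyte genes were among the most abundant genes of both libraries, beside ribosomal protein genes. *Dppa3* (Stella, a maternal-effect gene), *Omt2a*, *Uchl1* and the ribosomal protein gene *Rpl41* were among the 5 most abundant genes of 1 or both libraries. So were *Gdf9*, the ribosomal protein gene *Rps29* and the ubiquitin pseudogene *Gm1821*, for which the assignment of reads is uncertain. *Dppa3* stood at 10371 and 4524 FPKM in the wild type and cKO libraries, *Rpl41* at 9337 and 6332 FPKM, *Omt2a* at 9323 and 5448 FPKM, *Uchl1* at 6751 and 6067 FPKM and *Gm1821* at 6522 and 4189.9 FPKM. *Gdf9*, the growth factor whose promoter drove the Cre, stood at 5201 and 7658 FPKM, and *Rps29* at 3529.8 and 4648 FPKM.

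Among the 11816 genes at 1 FPKM or more in either library, 2149 were at least 2-fold higher and 1442 at least 2-fold lower in the cKO library. The genes that stood far lower included *Oog1* (oogenesin 1, an oocyte-expressed leucine-rich repeat gene; GRCm38 chromosome 12, 87602688 to 87608850), at 391.9 and 0.641 FPKM in the wild type and cKO libraries, 611-fold lower. *Pnpla3*, a lipid droplet acylhydrolase gene on chromosome 15, 84167837 to 84187236, stood at 158 and 0.304 FPKM, 519-fold lower. The kinase gene *Stk32a* stood at 20.2 and 0.0329 FPKM, and *Fcgbp*, which encodes a mucus protein, at 10.2 and 0.0535 FPKM. *Pold4*, a subunit gene of DNA polymerase delta, stood at 13.5 and 0.279 FPKM, and *Tctex1d1* at 14.7 and 0.958 FPKM. *Rnase6*, of the ribonuclease A family, stood at 13.9 FPKM in the wild type and was listed at 0 in the cKO library. For *Oaz1-ps* (166 FPKM, listed at 0 in the cKO), *Amd2* (13.7 and 0.0121 FPKM) and the histone gene *Hist1h2bg* (9.99 and 0.219 FPKM), near-identical copies elsewhere in the genome make the assignment of reads uncertain. *Oaz1*, the parent of *Oaz1-ps*, stood at 457 and 617 FPKM, and *Amd1*, the close relative of *Amd2*, at 24.8 and 80.9 FPKM. The relatives of *Oog1* differed far less than *Oog1* did. *Oog2* stood at 98.6 and 80.2 FPKM, *Oog3* at 593 and 337 FPKM and *Oog4* at 405 and 187 FPKM. *Oaz1*, *Amd1* and these relatives of *Oog1* were chosen after their values were seen.

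At the other end, 6 of the 12 genes with the largest ratios were listed at 0 in the wild type library. These were the beta-defensin genes *Defb41* (45.7 FPKM in the cKO; GRCm38 chromosome 1, 18250980 to 18265138) and *Defb48* (12.3 FPKM), *Arhgap8* (14.0 FPKM), the potassium channel gene *Kcnk18* (13.4 FPKM), *Gadd45g* of the growth arrest and DNA damage family (9.42 FPKM), and *Rspo1*, an enhancer of WNT signalling (8.41 FPKM). *Gpr83*, a G protein-coupled receptor gene, stood at 0.219 and 19 FPKM in the wild type and cKO libraries, 87.8-fold higher in the cKO. The CBP/p300-binding cofactor gene *Cited4* stood at 0.162 and 14.0 FPKM, the inducible HSP70 gene *Hspa1a* at 0.159 and 8.59 FPKM, and the monoacylglycerol lipase gene *Mgll* at 0.356 and 14.2 FPKM. *Nrtn*, a neurotrophic factor of the GDNF family, stood at 0.335 and 11.3 FPKM, and *Dio3*, the thyroid hormone-inactivating deiodinase, at 2.02 and 54.0 FPKM, 26.8-fold higher.

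**Figure D1:**
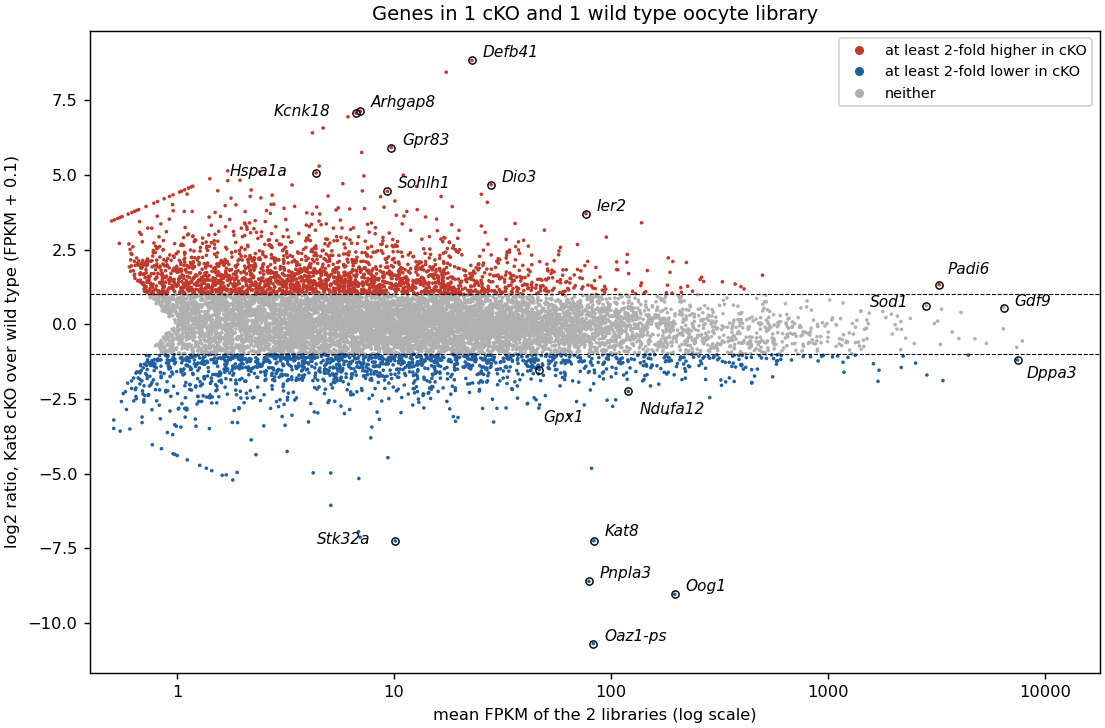
Each point is 1 of the 11816 genes at 1 FPKM or more in either library, with the mean FPKM of the 2 libraries on the x axis (log scale) and the log2 ratio of the cKO over the wild type library, after adding 0.1 FPKM, on the y axis. Dashed lines mark a 2-fold difference; 2149 genes lie at or above the upper line and 1442 at or below the lower one, and *Kat8* lies at -7.25.

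Of the genes past the 2-fold rule, 59.8% were higher in the cKO library, and the median log2 ratio of all genes was 0.06. The share depended on how the libraries were scaled: it was 72.6% with library sizes taken without the 50 most abundant genes, which moved the median of all genes to 0.26, and 74.7% with FPKM rescaled to TPM, that is, to the same total in both libraries, which moved it to 0.30. It was 55.9% with median-of-ratios scaling (2020 higher, 1592 lower) and 57.8% with the trend on length and GC content removed, with medians of 0.00 and -0.01.

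The genes of the complexes that contain KAT8 tended to be higher in the cKO library as a list, but the MSL subunit genes did not share this. The median log2 ratio of the 13 members of the MSL and NSL complexes was 0.75, at percentile 99.2 of 10000 random gene lists of the same size and expression, whose medians ran from -0.49 to 0.61 over their central 95%. Members at least 2-fold higher numbered 4: *Kansl3*, a scaffold subunit of the NSL complex (5.40 and 19.8 FPKM in the wild type and cKO libraries), *Hcfc1* (2.56 and 6.69 FPKM), the O-GlcNAc transferase gene *Ogt* (9.45 and 20.1 FPKM) and *Phf20l1* (2.46 and 5.16 FPKM). The 1 member at least 2-fold lower was *Msl3*, at 37.3 and 18.3 FPKM, just past the rule at a log2 ratio of -1.02. With a pseudocount of 1, 0 members were at least 2-fold lower. The other MSL subunit genes, *Msl1* (20.4 and 22.3 FPKM) and *Msl2* (7.24 and 8.68 FPKM), had log2 ratios of 0.13 and 0.26. These MSL genes were named after their values were seen. *Phf20l1* was just below the 2-fold rule with median-of-ratios scaling, at a log2 ratio of 0.98, and with the trend on length and GC content removed *Hcfc1* (0.78) and *Ogt* (0.98) were below it too.

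Nuclear-encoded genes of mitochondrial energy production were lower as a group in the cKO library. The 77 genes of oxidative phosphorylation had a median log2 ratio of -0.75, lower than all 10000 matched random lists (percentile 0); 20 were at least 2-fold lower, 1 at least 2-fold higher and 56 neither. The 4 members with the lowest ratios were all of complex I: *Ndufa12* stood at 198 and 41.6 FPKM in the wild type and cKO libraries, *Ndufb10* at 185 and 51.6 FPKM, *Ndufb4* at 544 and 157 FPKM and *Ndufb6* at 219.5 and 66.4 FPKM. Genes of the mitochondrial ribosome, which translates the proteins encoded by mitochondrial DNA, had a median of -0.67 over 77 members, also at percentile 0, with 27 at least 2-fold lower and 2 at least 2-fold higher. *Mrps12* stood at 77.0 and 13.3 FPKM, 5.81-fold lower, *Mrpl30* at 132 and 28.6 FPKM and *Mrpl22* at 245 and 58.5 FPKM, whereas *Mrps34* stood at 11.7 and 48.7 FPKM, 4.16-fold higher. These are short transcripts, and log2 ratios ran with transcript length across all genes. Random lists matched on expression and length had medians of -0.55 for oxidative phosphorylation and -0.31 for the mitochondrial ribosome. With the trend on length and GC content removed the medians of the 2 lists were -0.32 and -0.36. The mitochondrially encoded subunits were not analysed here.

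Antioxidant enzyme genes went both ways. The 47 members had a median log2 ratio of -0.29, at percentile 3.35, inside the range of the random lists as set beforehand; 8 were at least 2-fold lower, 6 at least 2-fold higher and 33 neither. *Ccs*, the copper chaperone of superoxide dismutase, stood at 15.1 and 2.46 FPKM in the wild type and cKO libraries, 6.14-fold lower, and the mitochondrial peroxiredoxin gene *Prdx3* at 20.1 and 4.42 FPKM, 4.54-fold lower. The glutathione peroxidase gene *Gpx1* stood at 69.3 and 24.1 FPKM, 2.87-fold lower. Haem oxygenase 1 (*Hmox1*) stood at 0.522 and 3.36 FPKM and sestrin 2 (*Sesn2*) at 0.702 and 3.01 FPKM, both more than 4-fold higher as FPKM. The cytosolic superoxide dismutase gene *Sod1*, at 2229 and 3425 FPKM, had a log2 ratio of 0.62 (1.15 less the length and GC trend); the mitochondrial form *Sod2*, at 6.33 and 6.38 FPKM, had one of 0.01. Catalase (*Cat*) was under 1 FPKM in both libraries, at 0.583 and 0.710. The list's percentile was 0.770 with a floor of 5 FPKM, 14.9 with no floor, 16.5 with random lists matched also on length and 21.9 with length and GC content. Its median was -0.12 less the length and GC trend and -0.05 with TPM.

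**Figure D2:**
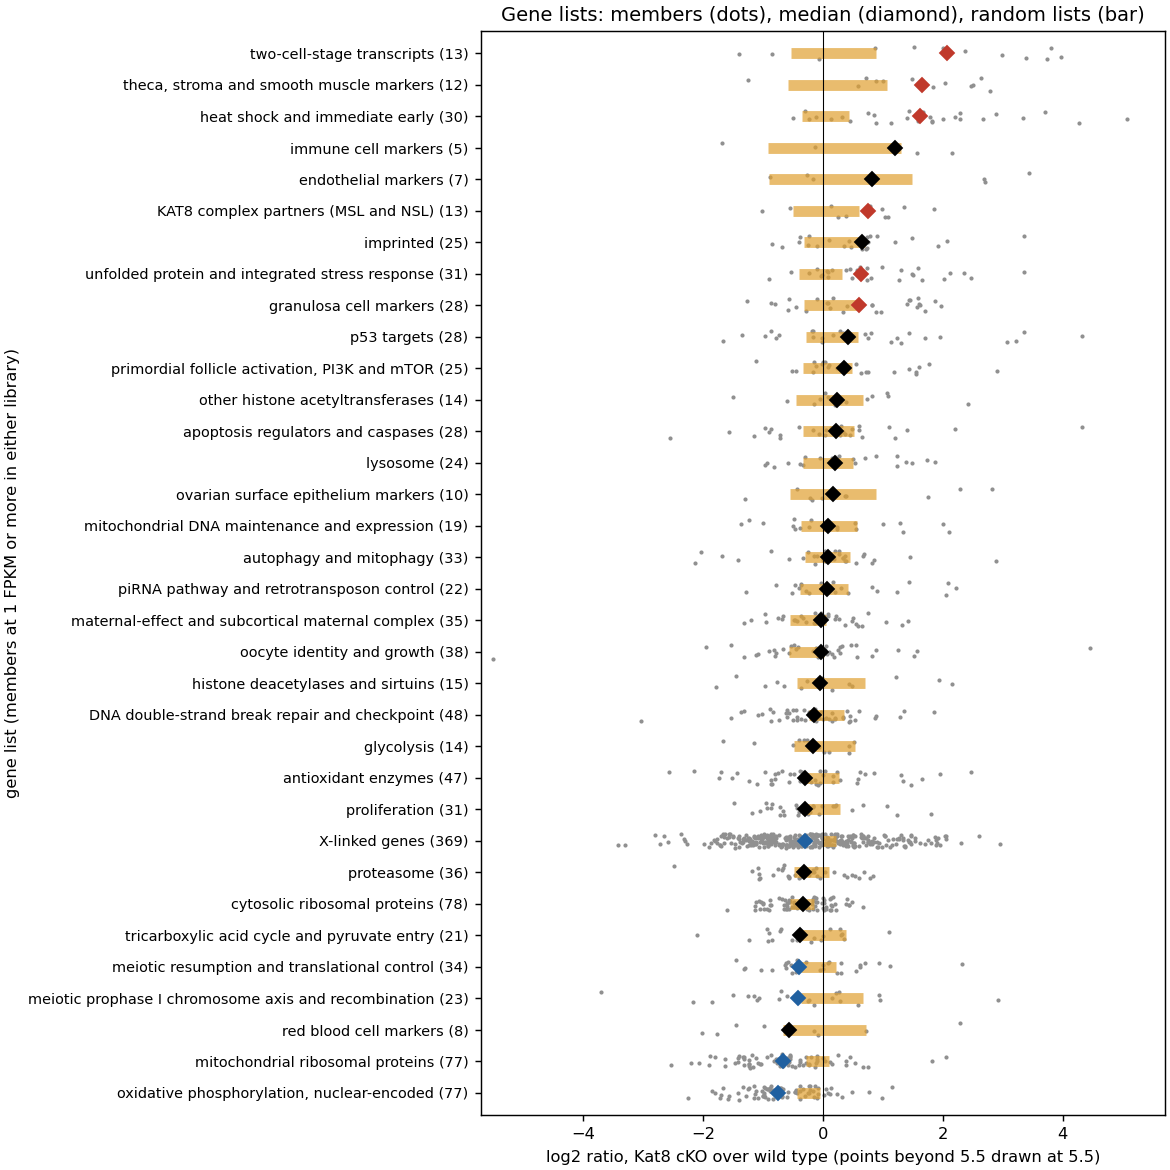
Log2 ratios of the cKO over the wild type library for each gene list, with 1 grey dot per member at 1 FPKM or more (values beyond 5.5 drawn at 5.5), a diamond for the median and a bar for the central 95% of the medians of 10000 random lists matched on size and mean expression. Blue and red diamonds are medians below and above that range; oxidative phosphorylation (-0.75) and mitochondrial ribosomal proteins (-0.67) lie lowest, and 2-cell-stage transcripts (2.07), stromal markers (1.66) and heat shock and immediate early genes (1.61) highest.

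Genes of oocyte identity were not shifted as a group, although single members differed by large factors. The 38 members had a median log2 ratio of -0.03 (percentile 94.2), with 4 at least 2-fold higher and 6 at least 2-fold lower. Besides *Oog1*, *Gm97* stood at 706 and 183 FPKM in the wild type and cKO libraries, whereas the germ cell transcription factor gene *Sohlh1* stood at 0.722 and 17.9 FPKM, 24.8-fold higher, and the germ cell RNA helicase gene *Ddx4* at 19.4 and 57.7 FPKM. The zona pellucida genes *Zp1*, *Zp2* and *Zp3* had log2 ratios of 0.32, 0.15 and 0.11; *Zp3* stood at 3073 and 3312 FPKM. *Gdf9* had a log2 ratio of 0.56, and its partner growth factor gene *Bmp15*, at 549 and 317 FPKM, one of -0.79. The 35 maternal-effect genes had a median of -0.02 (percentile 90.5). Of these, *Khdc3* (177 and 474 FPKM) and *Padi6* (1847 and 4638 FPKM), both of the subcortical maternal complex, were over 2-fold higher, and *Nlrp9c* (57.8 and 23.1 FPKM) and *Dppa3* over 2-fold lower. With TPM, which moved the median of all genes to 0.30, the medians of both lists were positive, at 0.21 and 0.22, and *Dppa3* was just short of the 2-fold rule, at a log2 ratio of -0.95.

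Both lists of meiotic genes were lower as groups in the cKO library. The 34 genes of meiotic resumption and translational control had a median log2 ratio of -0.40 (percentile 1.56; -0.16 with TPM, which moved the median of all genes to 0.30), with 4 at least 2-fold lower and 2 at least 2-fold higher. The Aurora kinase gene *Aurkb* stood at 7.47 and 2.67 FPKM in the wild type and cKO libraries, the cyclin gene *Ccnb3* at 5.54 and 2.16 FPKM and the deadenylase gene *Cnot7* at 79.0 and 32.1 FPKM (a log2 ratio of -0.97 less the length and GC trend), whereas *Zfp36l2*, which encodes an mRNA decay factor needed for oocyte maturation, stood at 6.76 and 34.3 FPKM, 5.07-fold higher. The 23 genes of the prophase I chromosome axis and recombination had a median of -0.41 (percentile 1.68; -0.01 less the length and GC trend), with 8 at least 2-fold lower. *Hormad2* stood at 1.86 and 0.0512 FPKM, *Tex12* of the synaptonemal complex at 24.4 and 5.33 FPKM and *Mei4* at 5.17 and 1.36 FPKM; the recombinase gene *Dmc1* was the 1 member at least 2-fold higher, at 0.115 and 1.54 FPKM. The prophase list no longer stood apart against random lists matched also on length and GC content (percentile 19.9). With that matching the resumption list still did (percentile 0.14), as with matching on expression and length (0.03). With matching on expression and GC content alone it stood at percentile 3.03.

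The list of p53 targets did not stand apart, although some members were higher in the cKO library. As fixed, it also holds *Trp53*, *Trp63*, *Trp73* and *Cdkn2a*, so it is not only a list of genes activated by p53. Of 28 members, 10 were at least 2-fold higher and 2 at least 2-fold lower in the cKO library, with a median log2 ratio of 0.42 inside the range of the random lists (percentile 90.7). With a floor of 5 FPKM the median was 0.14 (percentile 55.8), and less the length and GC trend it was 0.05. The BH3-only gene *Pmaip1* (Noxa) stood at 0.170 and 5.32 FPKM in the wild type and cKO libraries, the cell cycle inhibitor gene *Cdkn1a* (p21) at 0.0671 and 1.62 FPKM, the death receptor gene *Fas* at 0.0679 and 1.46 FPKM and the kinase gene *Plk2* at 0.387 and 3.98 FPKM, all under 1 FPKM in the wild type. Higher members at 5 FPKM or more in the larger library included *Ddit4* (15.9 and 52.4 FPKM) and *Gadd45a* (5.69 and 15.6 FPKM), named after their values were seen. The 2 lower members, named in the same way, were *Trp53* itself (9.85 and 3.04 FPKM) and the repair nuclease gene *Ercc5* (17.0 and 6.61 FPKM). The pro-apoptotic gene *Bax* stood at 40.4 and 22.2 FPKM, a log2 ratio of -0.86, and *Bbc3* (Puma) was at 0.0563 FPKM in the wild type and listed at 0 in the cKO library. The 28 apoptosis regulators and caspases had a median of 0.21 (percentile 72.9; -0.04 less the length and GC trend), with 5 at least 2-fold higher, including the survival gene *Mcl1* (5.72 and 26.7 FPKM), and 3 at least 2-fold lower, including the BH3-only gene *Bik* (164 and 28.0 FPKM) and cytochrome c (*Cycs*, 61.8 and 20.8 FPKM).

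Lists of stress-inducible genes were higher in the cKO library, although the abundant chaperone genes differed by less than 2-fold. The 30 heat shock and immediate early genes had a median log2 ratio of 1.61, above all 10000 matched random lists (percentile 100); 20 were at least 2-fold higher and 0 lower. Besides *Hspa1a*, *Ier2* stood at 10.8 and 142 FPKM in the wild type and cKO libraries, 13.1-fold higher, *Ier3* at 0.763 and 16.6 FPKM, and the AP-1 gene *Jund* at 3.24 and 33.6 FPKM. The abundant chaperone genes *Hsp90aa1* (1432 and 1580.1 FPKM) and *Hspa8* (561 and 477 FPKM) differed less. So did *Hspe1* (439 and 312 FPKM), *Hsph1* (120 and 202 FPKM) and *Dnajb1* (69.1 and 94.3 FPKM), with log2 ratios of -0.49, 0.75 and 0.45. These chaperone genes were named after their values were seen. In the 31 genes of the unfolded protein and integrated stress responses the median was 0.64 (percentile 99.985), with 11 at least 2-fold higher and 0 lower. These included *Herpud1* of endoplasmic reticulum-associated degradation (0.285 and 3.84 FPKM), the transcription factor gene *Xbp1* (1.36 and 8.06 FPKM), the co-chaperone gene *Dnajb9* (1.53 and 8.21 FPKM) and *Chac1*, a glutathione-degrading enzyme gene induced by ATF4 (2.44 and 11 FPKM). The lists of granulosa cell markers and of theca, stroma and smooth muscle markers also stood apart as higher, the former not in every setting. The latter had too few members to be set against random lists with a floor of 5 FPKM.

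Transcripts known from the 2-cell embryo were higher in the cKO library, at low levels. Of 13 members, 9 were at least 2-fold higher and 1 lower, with a median log2 ratio of 2.07 (percentile 100). They belong to multicopy families, *Usp17le* (0.112 and 3.22 FPKM in the wild type and cKO libraries), *Usp17lc* (0.122 and 2.88 FPKM), *Usp17lb* (0.274 and 3.82 FPKM) and *Gm13109* (0.258 and 4.91 FPKM) among them, whose reads cannot be assigned to 1 copy with certainty. The most abundant member, *Tcstv1*, named after its values were seen, was lower, at 211 and 80.0 FPKM. Among the 5 members at 5 FPKM or more the median no longer stood apart (percentile 37.9).

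Genes listed as markers of the cells that surround or accompany oocytes in the ovary were detected in both libraries. Whether their RNA came from those cells or from the oocytes was not tested. Granulosa cell markers had a median log2 ratio of 0.61 over 28 members (percentile 98.1). At least 2-fold higher in the cKO library were 10, including *Gatm* (0.393 and 1.83 FPKM in the wild type and cKO libraries), the activin subunit gene *Inhba* (4.62 and 17.2 FPKM) and *Gata6* (1.38 and 4.45 FPKM). The 1 member at least 2-fold lower was *Cdh2* (18.2 and 7.49 FPKM). The more abundant *Serpine2*, *Tnni3*, *Inha* and *Esr2* had log2 ratios of 0.17, 0.40, -0.10 and -0.45. *Cdh2* and these abundant markers were named after their values were seen. Markers of theca, stroma and smooth muscle had a median of 1.66 over 12 members (percentile 99.98), with 8 at least 2-fold higher and 1 lower. With a pseudocount of 1 the median was 0.86 (percentile 99.7), with 3 at least 2-fold higher. Among the 8 were the steroidogenic enzyme gene *Cyp11a1* (0.317 and 2.77 FPKM), the matrix genes *Sparc* (2.65 and 17.0 FPKM) and *Col1a2* (0.353 and 2.42 FPKM), and *Ogn* (0.112 and 1.10 FPKM). The lower member was *Myh11* (19.4 and 8.09 FPKM), the most abundant of the list, named after its values were seen. Endothelial markers had a median of 0.81 over 7 members (percentile 77.2; 0.15 less the length and GC trend), with *Sox17* at 0.0305 and 1.32 FPKM, *Cldn5* at 0.274 and 2.35 FPKM, *Egfl7* at 0.0879 and 1.11 FPKM and *Plvap* at 2.92 and 1.55 FPKM. Immune cell markers had a median of 1.20 over 5 members (percentile 96.4; 0.24 over 18 members, percentile 63.0, with no floor), with *Cd74* at 0.234 and 1.38 FPKM, *Laptm5* at 3.14 and 9.47 FPKM and *H2-Aa* at 1.77 and 4.18 FPKM, but the complement gene *C1qb* at 39.5 and 12.3 FPKM. Red blood cell markers had a median of -0.56 over 8 members (percentile 4.51). It was -0.15 (percentile 35.8) with a floor of 5 FPKM and -0.03 less the length and GC trend. The most abundant members were *Bpgm* (919 and 871 FPKM) and *Rhd* (93.0 and 83.9 FPKM), with log2 ratios of -0.08 and -0.15. Both were named after their values were seen. The globin genes *Hba-a1* (51.5 and 15 FPKM), *Hbb-b1* (9.94 and 2.39 FPKM) and *Hbb-b2* (17.3 and 6.26 FPKM) were lower in the cKO library. *Hba-a2*, named after its values were seen, was listed as higher (7.07 and 11.7 FPKM). *Hba-a1* and *Hba-a2* are near-identical copies, so the assignment of reads between them is uncertain and their directions cannot be set apart. The transferrin receptor gene *Tfrc* stood at 1.64 and 8.37 FPKM. Ovarian surface epithelium markers had a median of 0.17 over 10 members (percentile 56.1; -0.18 and percentile 27.2 with a floor of 5 FPKM), with *Lgals7* at 0.224 and 2.20 FPKM, *Krt18* at 0.668 and 3.67 FPKM, *Lrrn4* at 1.18 and 4.2 FPKM and *Aldh1a2* at 15.6 and 6.27 FPKM. The granulosa median no longer stood apart with a floor of 5 FPKM (percentile 51.6), with no floor, with a pseudocount of 1 or with random lists matched also on length. With a pseudocount of 1, *Ogn*, *Egfl7*, *Cd74* and *H2-Aa* fell short of the 2-fold rule, at log2 ratios of 0.92, 0.96, 0.95 and 0.90.

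X-linked genes were lower as a group in the cKO library. This comparison was made because the fly homologue of KAT8 acts in dosage compensation of the X chromosome. The 369 X-linked genes at 1 FPKM or more had a median log2 ratio of -0.30, with 76 at least 2-fold lower and 42 at least 2-fold higher. The 11446 autosomal genes had a median of 0.07, with 1365 at least 2-fold lower and 2107 higher. The X-linked median was lower than that of all 10000 random lists matched on expression (percentile 0) and lower than the median of every autosome, which ran from -0.04 to 0.16; with TPM it was -0.07 while that of all genes was 0.30. With the trend on length and GC content removed, the X-linked median was -0.13, still the lowest, next to -0.08 for chromosome 7. Lower X-linked genes with at least 5 FPKM included *Rgn* (24.1 and 3.36 FPKM in the wild type and cKO libraries), *Lage3* (71.2 and 11.2 FPKM), *Cxcr3* (9.20 and 1.46 FPKM) and *Magea10* (24.0 and 4.74 FPKM). *Amot* (1.38 and 7.19 FPKM), *Ammecr1* (5.05 and 21 FPKM), *Rbm10* (1.69 and 6.57 FPKM) and *Tmsb4x* (8.36 and 31.1 FPKM) were higher. These 8 were chosen after their values were seen, as the X-linked genes with the smallest and largest ratios.

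**Figure D3:**
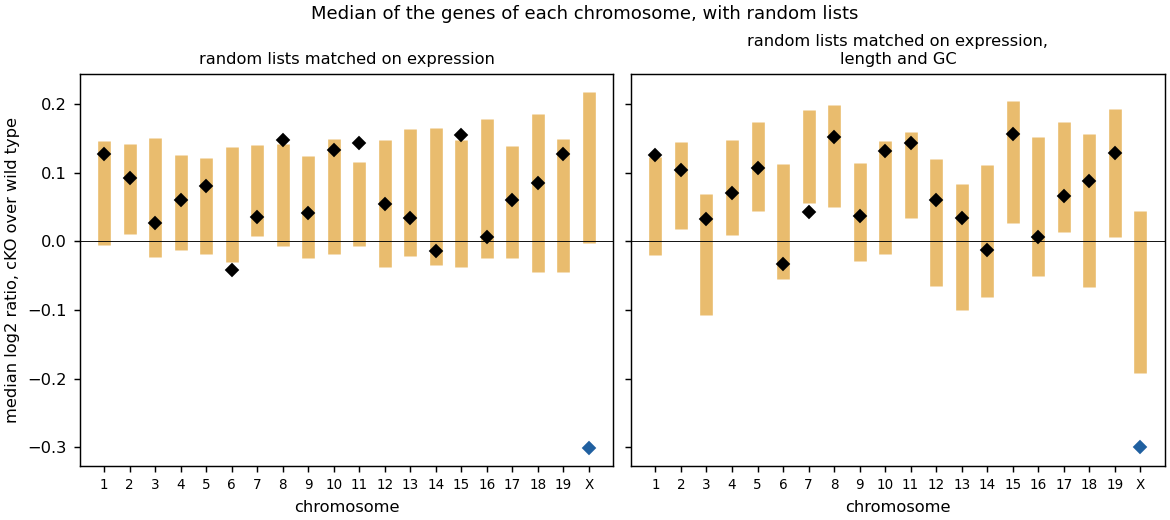
Median log2 ratio of the cKO over the wild type library for the genes of each chromosome (diamonds, X in blue), with the central 95% of the medians of 10000 random gene lists of the same size (bars), matched on expression in the left panel and on expression, transcript length and GC content in the right panel. The X chromosome, at -0.30 in the left panel, lies below its bar in both panels, and 4 of the 19 autosomes lie outside theirs in the left panel and 2 in the right panel.

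The lists of the authors held 500 genes higher and 358 genes lower in the cKO. The fold changes nearest to 1 were 2.00 and 0.497, and the largest FDR values 0.0497 and 0.0495, in these lists of the authors' deposited table. The rule of size used here was met by 498 of the higher and all 358 lower genes of the authors' deposited table. *Gadd45g* (9.42 FPKM in the cKO library) and *Pold4* (13.5 FPKM in the wild type library) had the smallest larger values in the higher and the lower list, respectively, of the authors' deposited table. Of the genes past the rule of size, 2735 lay outside those lists, 1928 of them with a larger value under 9 FPKM. The p-value in the authors' deposited table compares the 2 libraries and not the genotypes. Among genes that shared the whole-number parts of both FPKM values, 989 of 990 such pairs had 1 p-value in the authors' deposited table (within 1e-06), so that p-value took no account of gene length or of the decimals.

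The log2 ratios ran with properties of the transcripts. Across 11369 genes with a curated transcript, which are not independent replicates, Spearman's correlation was 0.227 with transcript length, 0.19 with GC content and -0.164 with mean FPKM. In the tenth of genes with the shortest transcripts the median log2 ratio was -0.57, and in the tenth with the longest it was 0.29.

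**Figure D4:**
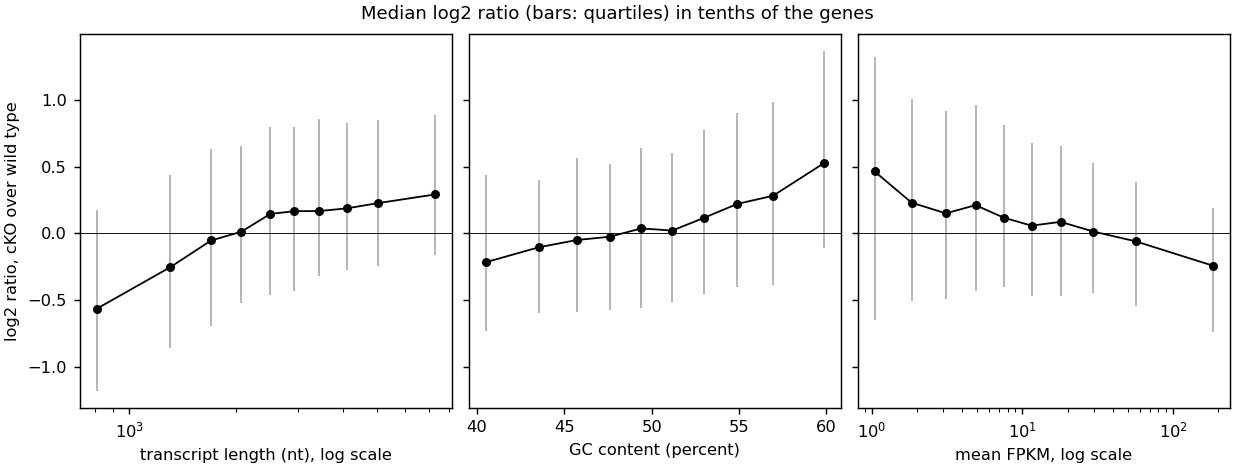
Median log2 ratio of the cKO over the wild type library (points) with quartiles (bars) in 10 groups of equal size of the 11369 genes ordered by transcript length in nucleotides (log scale), GC content in percent, and mean FPKM (log scale). The median runs from -0.57 to 0.29 with length, from -0.22 to 0.53 with GC content, and from 0.47 to -0.24 with mean FPKM.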

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

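FPKM rescaled to TPM, ratios less their trend on length and GC content, and random lists matched on GC content (alone or with length) were chosen after the data were seen; the other settings were planned. The cause of a difference between settings was not tested, except that a higher floor or a 4-fold rule counts fewer genes and a lower floor more. With the 4-fold rule, 570 genes were higher and 260 lower in the cKO library, with 173 and 73 of the genes in the authors' lists among them. With a floor of 5 FPKM, 1261 genes were higher and 953 lower, 3 lists stood apart as higher in place of 6 (30 lists kept at least 5 members), and the percentiles were 0.770 for antioxidant enzymes, 51.6 for granulosa cell markers and 37.9, on the other side of the middle, for 2-cell-stage transcripts. With no floor, 3392 genes were higher and granulosa cell markers stood at percentile 92.9. With a pseudocount of 1 these markers stood at 95.6.

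With random lists matched on expression and length, the percentiles were 3.15 for meiotic prophase, 96.8 for granulosa cell markers, 1.21 for DNA double-strand break repair, 0.5 for proliferation and 99.3 for cytosolic ribosomal proteins. With matching on expression and GC content, 2 lists stood apart as lower in place of 4, and the percentiles were 3.03 for meiotic resumption, 7.49 for meiotic prophase and 97.55 for imprinted genes. With matching on expression, length and GC content, they were 19.9 for meiotic prophase, 1.70 for proliferation and 98.96 for cytosolic ribosomal proteins. With random lists not matched on expression, 7 lists stood apart as lower, and the percentiles were 1.13 for antioxidant enzymes, 99.3 for imprinted genes, 97.6 for immune cell markers, 0.05 for cytosolic ribosomal proteins and 1.64 for the proteasome.

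In the other 317 combinations of a count or list with a setting, the result kept its side of its limit or, for a count, lay within 1.5 times the reported one. For the named genes, 640 combinations kept their side of the 2-fold rule, 13 fell short of it and 3 passed it that had not. Total counts, a counting interval of the ratio and a second unit were planned but not run, because only FPKM is given. No replicate could be left out and no paired analysis was possible because each group has 1 library. The unknown absolute depth limits what can be said of genes under about 1 FPKM.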

Other observations

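Random lists matched on GC content (alone or with length), the comparisons with granulosa cell and stromal markers (with their split by wild type level) and the comparison for 1 X chromosome were tests chosen after results had been seen. The genes named in the first 2 paragraphs were chosen after their values were seen. Among regulators of chromatin, the 14 other histone acetyltransferases had a median log2 ratio of 0.24 (percentile 72.8; 0.01 less the length and GC trend), with *Gtf3c4* at 0.712 and 4.26 FPKM and *Ep300* at 5.31 and 11.2 FPKM in the wild type and cKO libraries. The 15 deacetylases and sirtuins had a median of -0.05 (percentile 28.8; 0.19 with TPM), with *Sirt1* at 7.84 and 30.2 FPKM and *Sirt2* at 8.89 and 2.53 FPKM. In energy metabolism, mitochondrial DNA maintenance genes had a median of 0.09 (percentile 50.5), with the polymerase subunit gene *Polg2* at 2.65 and 11.8 FPKM and *Tfam* at 5.74 and 14.7 FPKM. Tricarboxylic acid cycle genes had a median of -0.38 (percentile 2.98; -0.13 with TPM, -0.18 less the length and GC trend), with the pyruvate carrier gene *Mpc1* at 24.5 and 5.66 FPKM, and glycolysis genes one of -0.17 (percentile 21.5; 0.08 with TPM), with *Gapdh* at 19 and 5.97 FPKM. Cytosolic ribosomal protein genes had a median of -0.34 (percentile 56.4; 0.10 less the length and GC trend), with *Rps14* at 1779.8 and 584 FPKM, and proteasome genes one of -0.32 (percentile 16.8; -0.07 with TPM, -0.13 less the length and GC trend), with the activator gene *Psme2* at 16.1 and 2.79 FPKM.

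Double-strand break repair genes had a median of -0.15 (percentile 7.40; 0.09 with TPM), with the end-joining factor gene *Nhej1* at 114 and 13.8 FPKM in the wild type and cKO libraries and the histone gene *H2afx* at 209.9 and 535 FPKM. Follicle activation, PI3K and mTOR genes had a median of 0.35 (percentile 91.2; 0.02 less the length and GC trend), with 7 of 25 at least 2-fold higher, *Rptor* (2.01 and 15.8 FPKM) and the p27 gene *Cdkn1b* (3.12 and 9.30 FPKM) among them. Autophagy genes had a median of 0.08 (percentile 50.4; -0.04 less the length and GC trend), with *Gabarapl1* at 0.866 and 7.04 FPKM and *Gabarapl2* at 23.8 and 5.34 FPKM. Lysosomal genes had a median of 0.20 (percentile 74.0), with the cholesterol transporter gene *Npc1* at 5.06 and 18.8 FPKM. In the piRNA and retrotransposon control list, with a median of 0.07 (percentile 60.3), *Tex19.1* stood at 45.1 and 191 FPKM, *Tex19.2* at 11.6 and 54.1 FPKM and *Piwil2* at 1.32 and 5.82 FPKM. Imprinted genes had a median of 0.65 (percentile 96.1), with *Smoc1* at 1.27 and 13.8 FPKM and *Ndn* at 0.562 and 2.68 FPKM. Proliferation genes had a median of -0.30 (percentile 4.26; -0.06 with TPM, -0.38 less the length and GC trend), with the cyclin gene *Ccne1* at 3.28 and 11.7 FPKM and the replication clamp gene *Pcna* at 59.0 and 25.9 FPKM.

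Oxidative phosphorylation and mitochondrial ribosomal protein transcripts were lower in the cKO library, and their transcripts are short (medians of 838 and 1223 nucleotides). Against random lists of like length the percentiles stayed at 0.36 and 0.04, of like GC content at 0 and 0, and of like length and GC content at 0.205 and 0.04, which argues against either property, or both, as the whole cause. A length and GC difference between the libraries may account for part of it, since removing that trend brought the medians from -0.75 and -0.67 to -0.32 and -0.36. A difference between the individual libraries in RNA quality, oocyte stage or collection, and an effect of the genotype, were not tested and stay open.

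Heat shock and immediate early transcripts were higher in the cKO library, and the percentile of 100 against lists of like length and GC content argues against these as the whole cause. The heat shock median exceeded that of the granulosa cell markers by 1.00 (bootstrap 95% interval 0.11 to 1.68), but 23 of these 28 markers were at 1 FPKM or more in the wild type library and 1 is in another list. *Serpine2* (251 and 281 FPKM), *Tnni3* (93.6 and 124 FPKM) and *Inha* (67.3 and 62.7 FPKM) are the most abundant, and such levels would hide a small share of added RNA; for the 21 markers under 10 FPKM in the wild type, a choice that itself favours higher ratios, the difference was 0.65 (-0.27 to 1.33). The difference from stromal markers was -0.0425 (-0.99 to 0.90), with 5 of 12 at 1 FPKM or more in the wild type and 1 in another list; *Sparc* was higher (2.65 and 17.0 FPKM) and the most abundant, *Myh11*, lower (19.4 and 8.09 FPKM). More RNA from granulosa or stromal cells therefore may contribute, handling of the tissue and the genotype were not tested, and none of these can be told apart with 1 library per group.

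X-linked transcripts were lower in the cKO library, and the percentile of 0 against random lists of like expression, length and GC content argues against length and GC content as the whole cause. They may account for a large part of it, since removing the trend on both brought the X-linked median from -0.30 to -0.13, and the central 95% of the random medians ran from -0.19 to 0.04 with that matching and up to 0.21 with matching on expression alone. A single X chromosome in place of 2 in all cKO oocytes, without compensation, would put the X-linked median 1 log2 unit below the autosomal one. The difference was -0.37 (bootstrap 95% interval -0.48 to -0.25 over genes), which argues against that case. A single X in part of the oocytes, or with partial compensation, would give a smaller shift, so the difference cannot decide on these. An effect of the genotype stays open as an untested hypothesis, beside oocyte stage and other differences between the individual libraries.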
